A study of Mus musculus with 6 samples.

How the data were processed

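Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map c-Myc, a basic helix-loop-helix leucine zipper transcription factor that binds DNA as a dimer with Max, in 3 mouse lung cancer cell lines named PB115, PB119 and PB120. The series holds 6 samples, a c-Myc ChIP and an input control (sonicated chromatin without immunoprecipitation) from each line. Per the labels' protocols, 20000000 cells per ChIP were fixed in 1% formaldehyde for 10 minutes, the reaction was stopped with 125 mM glycine, and chromatin was sheared with a probe sonicator for 4 minutes at 40% power. A c-MYC antibody was then used for the immunoprecipitation. Groups were taken from the sample titles: each line was a group with 1 ChIP library and 1 input library. No line had a replicate, so no value below carries an error between replicates.

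The files used here were 3 lists of peaks, 1 per ChIP library, each called on that library alone against the input of the same line. Inputs entered only through the authors' peak calling. The submitters' processing notes name Bowtie, SAMtools, MACS2 and the mouse genome build mm10. The versions of Bowtie and SAMtools are not given in the sources used here. Per the file headers, the caller was MACS 2.1.0.20140616 with a p-value cutoff of 1e-10, a model fold range of 15 to 100, a band width of 300 bp, an effective genome size of 2.70e+09, at most 1 tag kept per position, the larger library scaled to the smaller and a local background taken over 1000 and 10000 bp. Tags were 50 bases long per the file headers, and the modelled fragment lengths were 153 bp for PB115, 141 bp for PB119 and 149 bp for PB120.

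Each list gives a position, a summit and 4 values per peak. The deposited pileup is a signal, the ChIP fragment coverage at the summit after the authors scaled the ChIP to the depth of its input. Dividing it by the ratio of input to ChIP tags gave whole fragments, within 0.02 of an integer, at 100% of peaks in each list. The deposited fold is a ratio, pileup over local input background at the summit with 1 added to both, which allowed the background itself to be recovered. The deposited −log10 p-value is that of a Poisson test. Recomputing it from the pileup and the recovered background gave a median difference of 0.00122 or less in size, on the −log10 scale, in every list. The deposited −log10 q-value was present in every list although the file headers state that q was not calculated. All these are the authors' values for single peaks, and they were used to describe, rank or filter peaks within a list. Across lists, folds were compared by rank alone (Spearman's rho), and folds of the 3 lines at a gene are given beside each other as a description. Sizes were compared across lists only for ChIP fragments scaled to the number of ChIP tags and for background relative to the genome-wide level, in the tests of explanations.

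Depth after removal of repeated positions was 40494386 ChIP tags for PB115, 40726886 for PB119 and 32299364 for PB120, with 28380432, 37979638 and 26156520 input tags. The weakest summits listed held 24 fragments in PB115, 19 in PB119 and 21 in PB120. A site without a listed peak was therefore not detectable at the authors' cutoff, which is not evidence that c-Myc was absent there. Intervals given below are Wilson 95% intervals over peaks and cover counting error only. Peaks and genes are not independent replicates, and all p-values describe these 3 libraries, not the lines in general.

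Peaks of the 3 lists that overlapped by at least 1 bp were merged into regions. For shares of peaks and for single peaks named below, overlap with another line means a common merged region, which a peak of the third line can bridge. Chance sharing was taken from 100 random placements of each list within the annotated span of its own chromosomes. Genes came from a RefSeq gene table of assembly GRCm38.p6, the same assembly as mm10, with 49939 genes on chromosomes 1 to 19, X and Y, of which 21883 were protein-coding. The table has no strand. The planned window around the transcription start was therefore replaced by a window around either annotated end of a gene: a gene is called bound when a summit lies within 1000 bp of an end, and it is given its peak of highest fold. Among 4340 protein-coding genes longer than 20000 bp and at least 10000 bp from the next, both ends had such a summit in 2 genes in PB115, 6 in PB119 and 0 in PB120, against 779, 1282 and 478 genes with a summit at a single end. The peak of highest fold can differ between lines: among the 3152 genes bound in all 3 lines, these peaks did not all overlap in 300. Neighbouring genes can share a summit: 32.2%, 29.1% and 33.2% of the bound genes of PB115, PB119 and PB120 had the same peak of highest fold as another gene.

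Overlaps of bound genes and gene lists were tested with two-sided Fisher's exact tests, and fold enrichment of shared and line-specific peaks with two-sided permutation tests of 100000 resamples on medians, all with Benjamini-Hochberg adjustment and a threshold of 0.05. The 19 gene lists were fixed before the data were examined: ribosome biogenesis, ribosomal proteins, translation factors and aminoacyl-tRNA synthetases, nucleotide and polyamine synthesis, glycolysis and glucose uptake, mitochondrial biogenesis and chaperones, cell cycle and DNA replication, mitotic kinases and spindle, MYC network, neuroendocrine and small cell lung cancer regulators, Notch pathway and non-neuroendocrine markers, alveolar and airway epithelium markers, immune cell markers, fibroblast and endothelial markers, circadian genes (drawn up around E-boxes), genes repressed by MYC with MIZ1, p53 targets and apoptosis, lysosome and autophagy, and silent chemosensory receptors. Symbols matched the gene table for all but 2 of the 546 genes listed by name, which stand in the Notch list under older symbols of genes it also holds under newer ones.

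Genes named in the text follow a rule fixed before the data were examined. It takes the 12 genes bound in all 3 lines with the highest lowest rank of fold, the 3 members of each gene list bound in most lines, the 5 genes bound in each line alone with the highest fold, the 3 peaks of highest pileup per line, and genes given whatever their result, of which 17 are reported: Myc, Mycn, Mycl, Max, Neurod1, Insm1, Pou2f3, Yap1, Rest, Nfib, Aurka, Aurkb, Ncl, Cad, Odc1, Cdk4 and Nr1d1. Other names given in counts of list members, and Pvt1, were chosen after their values were seen. The result of 1 further gene of the rule and that of 1 gene group chosen later are not reported here.

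Alternatives set before the data were examined were windows of 500 and 5000 bp, the ends of all annotated genes, a fold of at least 5, a q of 1e-5 or smaller, chromosomes 1 to 19, X and Y alone, the same number of peaks per list, reciprocal overlap of at least 50%, summits within 100 bp, leaving out each line, and pileup or −log10 q in place of fold. Those added afterwards were a p of 1e-20 or smaller, summits anywhere in a gene, removal of peaks with an input background over 5 times the genome-wide level, and removal of chromosome 8. The planned share of peaks with an E-box, the planned background of CpG-rich promoters and the planned classes by exon, intron and UTR need a genome sequence or transcript models and were not analysed here.

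The scripts were tested on simulated data: of 2000 planted shared regions 2000 were found in all lists, and a summit planted at the end of 2000 genes was assigned to 2000 of them. Over 100 draws in which 80% of the members of 1 of 16 gene lists were bound, the planted list was called in 100% of its tests and the lists without shared members in 0.133% of theirs, with all 21883 genes as background. Planted regions were identical in all lists and stood at genes far from their neighbours. Other bound genes were drawn evenly, without shared summits or promoter preference. These runs therefore check the code and not error rates in the real lists. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.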

Results

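Binding of c-Myc was profiled by ChIP-seq in the mouse lung cancer cell lines PB115, PB119 and PB120, with 1 ChIP library and 1 matched input library per line. The series states as its purpose only that Myc was mapped in these lines, so the comparisons below ask where the factor was found, which sites and genes the lines had in common, and which they did not. The ChIP libraries held 40494386 tags for PB115, 40726886 for PB119 and 32299364 for PB120 after filtering. The authors' lists held 7830 peaks for PB115, 13527 for PB119 and 5168 for PB120, with median lengths of 270, 286 and 247 bp. Median fold enrichment over input was 9.59 in PB115, 9.80 in PB119 and 8.96 in PB120, at a median of 49 fragments, 43 fragments and 41 fragments per summit. The highest fold was 46.3 in PB115, 60.9 in PB119 and 39.5 in PB120. There were no replicates, so differences between lists were not set against a spread between libraries of 1 line. Fold enrichments are the authors' values and rank peaks within a list, and their sizes are not compared between lines.

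Of the 12 genes that ranked highest for c-Myc in all 3 lines, 4 encode ribosomal proteins or factors of ribosome production. Ncl, which encodes the nucleolar protein nucleolin, had a fold of 34.2 in PB115, 46.6 in PB119 and 23.4 in PB120. Ppan and Fbl, which act in ribosomal RNA processing, had folds of 41.9 and 33.3 in PB115, 56.3 and 37.3 in PB119, and 22.9 and 22.5 in PB120, where the Fbl value came from a peak at the opposite end of the gene that also lay within 1000 bp of Dyrk1b. Rpl10a, a protein of the large ribosomal subunit, had folds of 35.6, 42.0 and 23.3 in PB115, PB119 and PB120. Klf16, a zinc finger transcription factor gene, had 46.3, 52.8 and 23.9 in the same order, and its peak was the highest of the PB115 list. Pcbp1, an RNA-binding protein gene, had 38.2, 55.2 and 37.1. A single summit inside B3galt6, a galactosyltransferase gene, and within 1000 bp of Sdf4 had 39.6, 51.2 and 30.2. The other genes of the leading 12 were Ap4m1 with folds of 32.9, 44.9 and 26.7, G6pc3 with 32.6, 40.5 and 24.8, Calm3 with 32.2, 42.4 and 23.1, and Atf7 with 28.8, 35.5 and 22.7. The Ap4m1 summits lay 964, 999 and 931 bp outside the gene in PB115, PB119 and PB120, near the limit of the 1000 bp window.

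In mm10 coordinates, the PB119 peak at Ncl spanned 86358214 to 86360153 on chromosome 1, with its summit inside the gene 667 bp from an end. At Ppan it spanned 20887762 to 20888790 on chromosome 9, with the summit 68 bp inside the gene. At Rpl10a it spanned 28328130 to 28329382 on chromosome 17, and at Klf16 80576321 to 80578721 on chromosome 10, where the summit was 751 bp outside the gene. The shared summit of B3galt6 and Sdf4 lay at 155992406 on chromosome 4, 272 bp from the end of B3galt6 and 437 bp from that of Sdf4.

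Of 14193 merged regions, 3748 (26.4%) had a peak in all 3 lines, against a median of 0 and a highest value of 1 in 100 random placements. Random placement ignored the preference of summits for gene ends, so it shows only that sharing exceeded a uniform scatter. Another 3502 regions were listed in PB115 and PB119, 617 in PB119 and PB120, and 29 in PB115 and PB120. PB119 alone listed 5591 regions, PB120 alone 567 and PB115 alone 139. Of the PB115 peaks, 97.9% (95% interval 97.5 to 98.2) lay in a merged region with a PB119 peak and 52.0% (50.8 to 53.1) in one with a PB120 peak. PB120 peaks lay in a merged region with a PB119 peak in 88.5% of cases (87.6 to 89.3) and with a PB115 peak in 77.1% (75.9 to 78.2). Leaving out PB120 raised the number of regions common to the remaining lines from 3748 to 7255, and a stricter p of 1e-20 or a reciprocal overlap of 50% lowered it to 2419 or 2186.

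**Figure D1:**
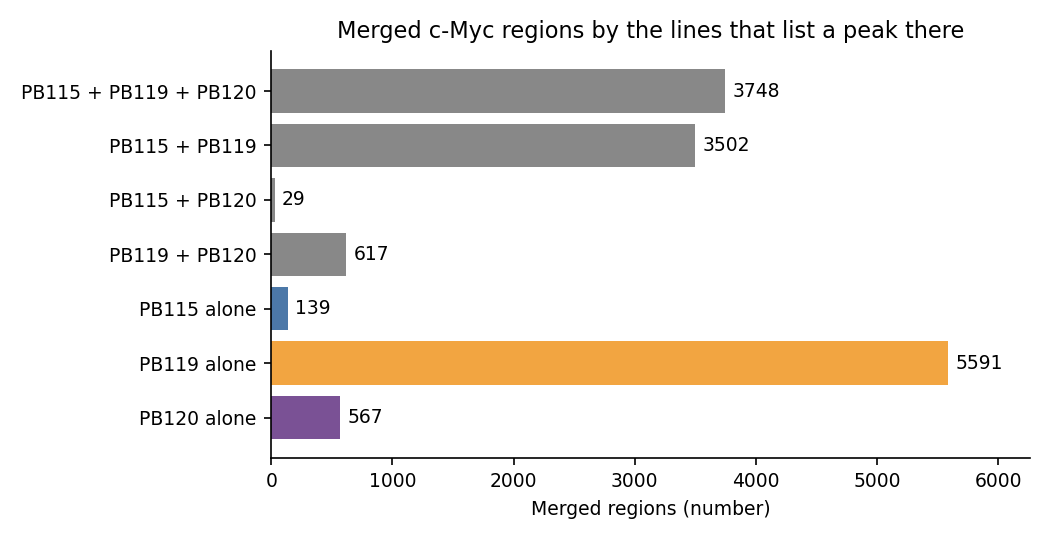
Number of merged c-Myc regions (horizontal axis) by the combination of lines that list a peak there (vertical axis), with grey bars for regions of several lines and coloured bars for regions of 1 line. Regions of all 3 lines number 3748 and those of PB119 alone 5591, while PB115 alone has 139.

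Sharing was more frequent among peaks of higher fold. Of the 20% of PB115 peaks with the highest fold, 100% lay in a merged region with a PB119 peak and 84.9% in one with a PB120 peak. Of the 20% with the lowest fold, 95.2% and 35.6% did. In PB119 the share found in PB120 was 75.7% among the top 20% and 12.5% among the bottom 20%. In PB120 the share found in PB119 was 94.6% at the top and 83.2% at the bottom. Peaks common to all lines had a median fold of 11.3 against 7.67 for line-specific peaks in PB115, a log2 difference of 0.56. The medians were 15.9 and 7.99 in PB119 (log2 difference 0.99) and 9.32 and 8.20 in PB120 (log2 difference 0.18). Each of these 3 differences had a permutation p of 1e-05, the smallest that 100000 resamples can give, also after adjustment. A peak counted as shared only where the site also passed the authors' cutoff in the other libraries. Weak sites are lost more easily at that cutoff, so shared peaks can have the higher fold even where the lines bind the same sites. The fold comparisons of this paragraph therefore describe the lists and cannot tell line-specific binding from sites missed at the cutoff. Across the 3748 common regions, which are not independent replicates, Spearman's rho between fold enrichments was 0.77 for PB115 and PB119, 0.41 for PB115 and PB120, and 0.40 for PB119 and PB120. Fold also depends on input background, with medians over peaks of 1.59, 1.51 and 1.86 times the genome-wide level in PB115, PB119 and PB120. Its quartiles were 1.35 to 1.87, 1.34 to 1.88 and 1.47 to 2.48. Whether the lower rho with PB120 reflects background or a different order of c-Myc binding was not tested.

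Most c-Myc summits lay close to an end of a protein-coding gene. Within 1000 bp of an end were 63.4% of summits in PB115 (95% interval 62.3 to 64.4), 59.6% in PB119 (58.8 to 60.4) and 62.6% in PB120 (61.3 to 63.9), against averages of 3.28%, 3.24% and 3.25% in random placements. Summits deeper inside a gene made up 24.2%, 26.5% and 22.6%, and those outside genes 12.4%, 13.9% and 14.8%, where random placement gave averages between 57.5% and 57.6%. The median distance of the gene-end summits was 137 bp in PB115, 152.5 bp in PB119 and 95 bp in PB120. Summits at gene ends were more often common to all 3 lines than other summits. The shares were 57.8% against 40.8% in PB115 (Fisher odds ratio 1.99), 33.0% against 20.5% in PB119 (1.91) and 85.9% against 60.7% in PB120 (3.95), with adjusted p of 3.18e-48, 2.90e-58 and 6.26e-92. Peaks at gene ends also had a higher median fold than the others, 9.91 against 9.09 in PB115, 10.5 against 8.97 in PB119 and 9.07 against 8.72 in PB120. Fold was not held equal, so an effect of position alone was not tested. The shares near gene ends changed with the window, to between 49.6% and 56.1% at 500 bp and between 74.6% and 77.4% at 5000 bp.

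At gene level, c-Myc was found at 5172 genes in PB115, 7723 in PB119 and 3598 in PB120, which is 23.6%, 35.3% and 16.4% of the 21883 protein-coding genes. A set of 3152 genes was bound in all 3 lines, where independent lists of the same sizes would share 300. PB115 and PB119 had 5115 bound genes in common against 1825 for independent lists (Fisher odds ratio 485), PB119 and PB120 had 3513 against 1270 (odds ratio 138), and PB115 and PB120 had 3168 against 850 (odds ratio 59.9). In all 3 pairs the Fisher p was below the smallest value the software prints. Independent lists treat every coding gene as equally likely to be bound, so a preference for some genes common to all lines was not allowed for. Of the genes named below, Aurka, Cad, Eif4a1, Aimp2, Dbp, Atp6v1a, Bcl2l11, Arid2, Hrc, Mei1 and Armc5 had a summit that also lay within 1000 bp of another coding gene. Among the PB115 genes, 98.9% were bound in PB119 and 61.3% in PB120. Among the PB120 genes, 97.6% were bound in PB119 and 88.0% in PB115. With the same number of peaks in each list, PB115 and PB119 had 3278 bound genes in common, PB119 and PB120 2735, and PB115 and PB120 2637.

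Genes bound in a single line were few in PB115 and PB120, with 41 and 69 genes, and numbered 2247 in PB119. The highest of PB120 was Pigv, a gene of glycosylphosphatidylinositol anchor synthesis, with a fold of 26.4 and 109 fragments at 133659413 to 133659774 on chromosome 4. Bpifb5 followed with a fold of 16.3, the orphan receptor gene Gpr61 with 13.7, the thyroid hormone receptor gene Thra with 13.2 and Faf2 with 12.8. None of these 5 peaks overlapped a peak of another line. In PB119 the highest were Mei1 with 21.2, Armc5 with 19.9, Fbxo17 with 16.3, the tRNA splicing endonuclease gene Tsen15 with 16.2 and the protein translocation gene Sec63 with 15.7. The peaks at Mei1 and Armc5 overlapped peaks of both other lines whose summits fell outside the 1000 bp window, and those at Fbxo17, Tsen15 and Sec63 overlapped none. In PB115 the highest were Arid2 with 14.1, Hrc with 12.2, Zbtb7b with 10.7, Rasd2 with 10.1 and Usp4 with 10.1. Only Hrc and Zbtb7b of these 5 had a peak without overlap in another list. Counting genes whose peak overlapped no other list left 18 of 41 in PB115, 2236 of 2247 in PB119 and 60 of 69 in PB120.

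Most genes of the ribosome and protein synthesis lists were bound in each line. Of 54 ribosome biogenesis genes, 46 were bound in all 3 lines, with 51 in PB115, 50 in PB119 and 47 in PB120, and Ubtf, Noc3l and Nat10 were bound in none. These exceptions hold for the 1000 bp window only: at 5000 bp, or with summits inside genes counted, 100% of the list was bound in PB115 and in PB119. Gar1, which encodes a protein of small nucleolar ribonucleoproteins, had folds of 40.8, 43.2 and 21.6 in PB115, PB119 and PB120. Of 64 ribosomal protein genes, 59, 61 and 53 were bound in the 3 lines, 52 of them in every line. Rpl13a had folds of 30.4, 48.9 and 17.0, and Rps19 had 21.6, 30.6 and 15.8. Of 38 translation factor and aminoacyl-tRNA synthetase genes, 34, 34 and 28 were bound, among them the RNA helicase gene Eif4a1 with folds of 26.6, 37.6 and 21.2, Aimp2 with 24.5, 41.9 and 19.1, and Eif4b with 18.4, 24.5 and 22.5. Odds ratios against all other coding genes were 55.5, 23.1 and 34.6 for ribosome biogenesis, 38.6, 37.6 and 24.8 for ribosomal proteins, and 27.6, 15.6 and 14.3 for the translation list. The largest adjusted p of these 9 Fisher tests was 2.00e-11. Here and below, lists were compared with all other coding genes and not with CpG-rich or active promoters. Whether calls in either direction reflect promoter class or activity of the members, and not a choice by c-Myc, was therefore not tested.

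Metabolic and mitochondrial genes were also bound more often than other genes. Of 32 nucleotide and polyamine synthesis genes, 24 were bound in PB115, 30 in PB119 and 22 in PB120 (odds ratios 9.73, 27.6 and 11.2). Srm, the spermidine synthase gene, had folds of 30.8, 41.5 and 19.2. Atic, of purine synthesis, had 19.8, 37.3 and 18.7, and Cad, which starts pyrimidine synthesis, had 24.4, 36.0 and 15.9. Of 32 mitochondrial biogenesis and chaperone genes, 29, 31 and 24 were bound (odds ratios 31.4, 57.1 and 15.3). The mitochondrial chaperonin genes Hspd1 and Hspe1, which share a summit, had folds of 27.2, 30.7 and 20.8, and the import receptor gene Tomm20 had 16.8, 25.0 and 17.9. The largest adjusted p of these 6 tests was 3.81e-09. Glycolysis and glucose uptake had 10, 15 and 9 of 21 genes bound (odds ratios 2.94, 4.59 and 3.82; adjusted p 0.0241, 0.00193 and 0.00707). Hk2, a hexokinase gene, had folds of 26.4, 31.7 and 13.6, Pkm, a pyruvate kinase gene, had 20.0, 21.1 and 13.0, and Pgam1 had 19.8, 24.2 and 12.2. Ldha, Aldoa and Slc2a3 were among the 6 genes of this list without a summit within 1000 bp of an end in any line. The share of the list bound in PB119 was 85.7% at 5000 bp and 90.5% with summits inside genes counted, so some of these 6 had a summit farther away or inside. The glycolysis list was called in 4 of 6 alternative settings in each line, and its adjusted p reached 0.0936, 0.181 and 0.259 in PB115, PB119 and PB120.

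Lysosomal and clock genes were over-represented in all 3 lines as well. The circadian list was drawn up around control of the clock through E-boxes, a motif that MYC also binds, and 13, 16 and 11 of its 18 genes were bound (odds ratios 8.42, 14.7 and 8.01; adjusted p 4.81e-05, 1.12e-05 and 6.21e-05). Nr1d1, a nuclear receptor of the clock, had folds of 28.6 in PB115, 27.3 in PB119 and 20.3 in PB120, Per2 had 17.0, 19.3 and 16.0, and Dbp had 14.9, 21.3 and 16.2. Arntl and Npas2 had no summit within 1000 bp of an end in any line, and at 5000 bp 94.4% of the list was bound in PB119. Of 26 lysosome and autophagy genes, 14, 20 and 11 were bound (odds ratios 3.78, 6.12 and 3.74; adjusted p 0.00184, 7.37e-05 and 0.00317), with Map1lc3b at 18.6, 23.0 and 14.5, Ctsd at 11.0, 10.7 and 12.5, and Atp6v1a at 10.8, 17.1 and 9.25. The lysosome call for PB120 was lost without chromosome 8 (adjusted p 0.0922, range over 6 alternatives 0.00196 to 0.0922), and that for PB119 with the same number of peaks per list (0.150, range 7.71e-06 to 0.150).

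Proliferation genes were bound in part. Of 36 cell cycle and DNA replication genes, 20 were bound in PB115, 27 in PB119 and 13 in PB120 (odds ratios 4.05, 5.52 and 2.88; adjusted p 8.76e-05, 4.53e-06 and 0.00858). The call was lost in 1 of 6 alternatives in PB115, with equal list lengths (adjusted p 0.0589, lowest of the range 1.49e-06), and in 1 in PB120, at a p of 1e-20 (0.333, lowest 0.00126). Ccne2, the cyclin E2 gene, had folds of 24.8, 44.3 and 19.6, and Cdk4 had 14.8, 17.6 and 12.3. Cks2 had 23.6 in PB115 and 31.9 in PB119 at a summit shared with Secisbp2, and 10.8 in PB120 at another peak, at the opposite end of the gene. Of 20 mitotic kinase and spindle genes, 6, 13 and 3 were bound, and only PB119 passed the test (odds ratio 3.41, adjusted p 0.0134), against odds ratios of 1.39 in PB115 (adjusted p 0.655) and 0.897 in PB120 (adjusted p 1.00). Aurka, the Aurora kinase A gene, had folds of 39.3, 31.5 and 14.1, Birc5 had 19.5, 25.8 and 13.4, and Bub1b had 14.8, 19.7 and 8.18. Aurkb had a peak in PB115 (8.89) and PB119 (13.8) and none within 1000 bp of an end in PB120. The PB119 call for the mitotic list held in 2 of 6 alternatives, with adjusted p from 0.00559 to 0.445. With the same number of peaks per list the share bound in PB119 fell from 65.0% to 25.0%, the value PB115 also had there.

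**Figure D2:**
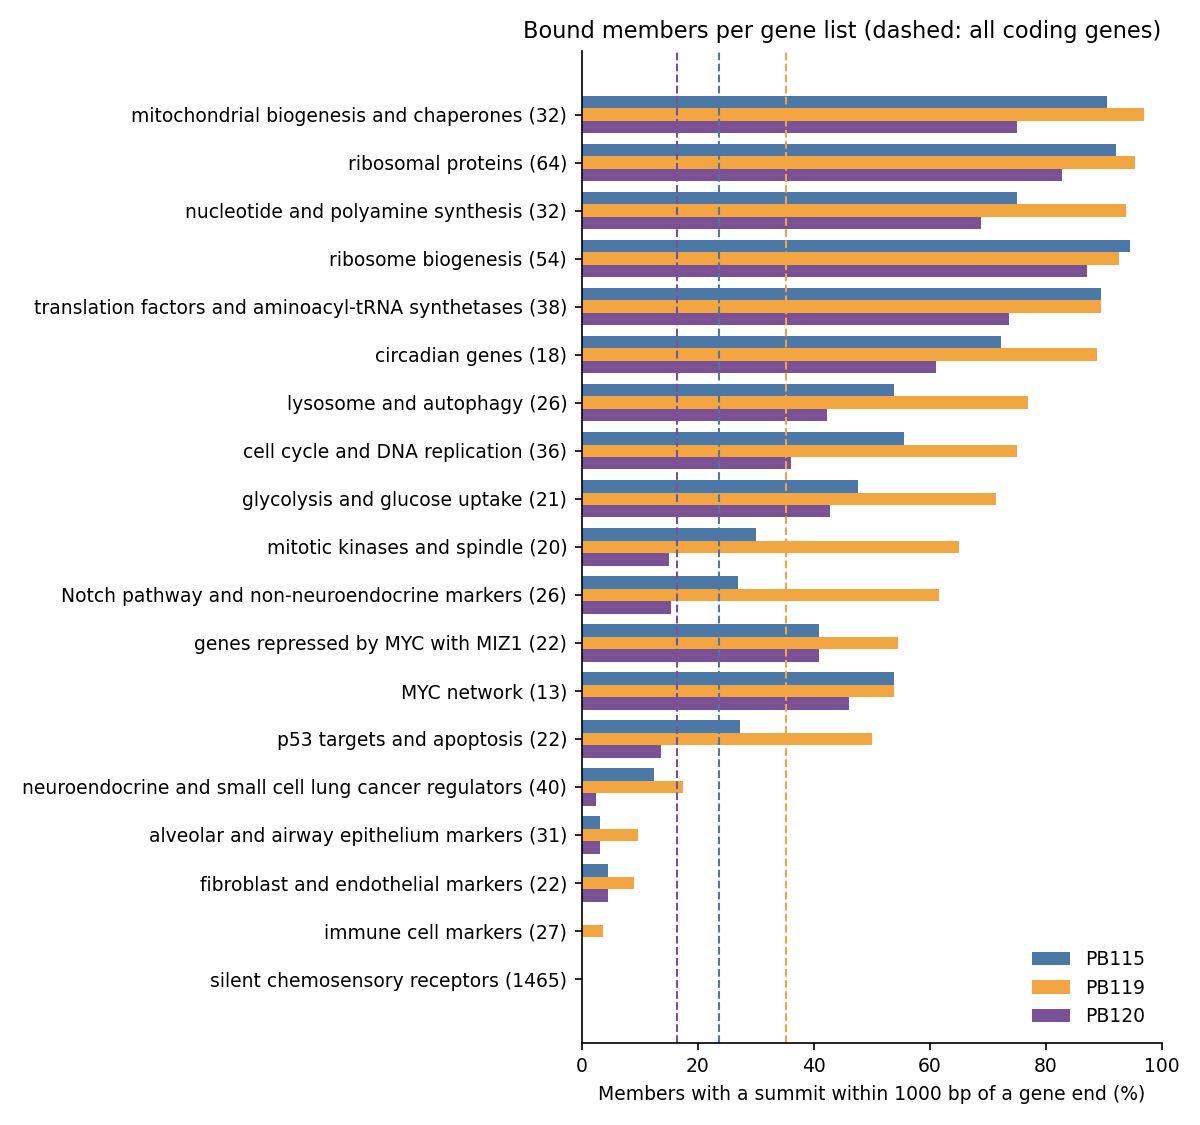
Percent of the members of each gene list with a c-Myc summit within 1000 bp of a gene end (horizontal axis) in PB115, PB119 and PB120 (coloured bars), with list sizes in parentheses and dashed lines for the share among all coding genes. Ribosomal protein genes reach 92.2%, 95.3% and 82.8%, and neuroendocrine regulators 12.5%, 17.5% and 2.50%.

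Few genes of the neuroendocrine list had a c-Myc summit within 1000 bp of an end. Of 40 neuroendocrine and small cell lung cancer regulators, 5 were bound in PB115, 7 in PB119 and 1 in PB120 (odds ratios 0.461, 0.388 and 0.130; adjusted p 0.159, 0.0259 and 0.0155). Neurod1, Insm1 and Pou2f3, transcription factors that mark subtypes of small cell lung cancer or neuroendocrine cells, had no peak within 1000 bp of either end in any line. Nfib, a nuclear factor gene, was bound in all 3 lines with folds of 13.1, 24.3 and 9.49. Sox2 had 11.1 in PB115 and 12.5 in PB119, and Yap1, a Hippo pathway coactivator gene, had 9.45 and 11.4, both without a peak in PB120. Rest, a repressor of neuronal genes counted in the Notch list and not among these 40 genes, had 7.02 in PB115, 10.2 in PB119 and no peak in PB120. The PB119 call held in 2 of 6 alternatives (adjusted p 0.0171 to 0.643), with 37.5% of the list bound at 5000 bp, 35.0% with summits inside genes counted and 5% with the same number of peaks per list, and the PB120 call in 5 (0.00273 to 0.158).

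Of 26 genes of the Notch pathway and non-neuroendocrine markers, 7 were bound in PB115, 16 in PB119 and 4 in PB120 (odds ratios 1.19, 2.94 and 0.924), and only PB119 passed (adjusted p 0.0114, against 0.685 and 1.00). That call held in 2 of 6 alternatives, with adjusted p from 0.00417 to 1.00. With the same number of peaks per list 11.5% of the list was bound in PB119 in place of 61.5%, and the odds ratio fell from 2.94 to 0.588. PB115 was called in 1 alternative (adjusted p 0.0393 to 1.00), and in PB115 and PB120 the side of 1 on which the odds ratio lay changed with the setting. Notch2 had folds of 21.1, 27.6 and 9.61, the matricellular protein gene Ccn1 had 9.56, 13.5 and 8.59, and Cd44 had 9.23 in PB115, 12.3 in PB119 and no peak within 1000 bp of an end in PB120.

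Markers of alveolar and airway epithelium, immune cells, fibroblasts and endothelium were rarely bound. Of 31 alveolar and airway epithelium markers, 1, 3 and 1 were bound (odds ratios 0.108, 0.196 and 0.169; adjusted p 0.00845, 0.00395 and 0.0630). Abca3, the lipid transporter gene of alveolar type II cells, was bound in all lines with folds of 16.6, 26.8 and 21.1 at a summit shared with Abca17, and Scgb1a1 (6.97) and Cav1 (6.14) had peaks in PB119 alone. The PB115 call for this list held in 3 of 6 alternatives (adjusted p 0.00476 to 0.0884) and the PB119 call in 6 (0.00329 to 0.0486), while PB120 was called in 2 (0.0193 to 0.296). Of 27 immune cell markers none was bound in PB115 or PB120, and Cd68 was bound in PB119 with a fold of 4.67, at a summit that also lay within 1000 bp of Eif4a1 (odds ratios 0, 0.0704 and 0 in PB115, PB119 and PB120; adjusted p 0.00211, 0.000384 and 0.0226). The PB120 call for immune markers held in 4 of 6 alternatives (adjusted p 0.00573 to 0.121). Of 22 fibroblast and endothelial markers, 1, 2 and 1 were bound (odds ratios 0.154, 0.183 and 0.242; adjusted p 0.0529, 0.0174 and 0.185), namely Erg in all lines, with folds of 7.43, 7.78 and 9.50, and Col1a1 in PB119 with 7.87. The PB119 call for this list held in 4 of 6 alternatives (adjusted p 0.00872 to 0.0985), and PB115 was called in 2 (0.0222 to 0.391). Among 1465 chemosensory receptor genes, which are silent outside sensory tissue, Vmn1r4 alone was bound, with folds of 12.7, 18.7 and 11.1 at a summit it shares with Nt5c3, and the odds ratios of the list were 0.00201, 0.00112 and 0.00319, with a largest adjusted p of 2.54e-115.

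The MYC network itself was divided. Of its 13 genes, 7 were bound in PB115, 7 in PB119 and 6 in PB120 (odds ratios 3.77, 2.14 and 4.36; adjusted p 0.0243, 0.272 and 0.0174). The calls for PB115 and PB120 each held in 5 of 6 alternatives (adjusted p 0.00662 to 0.0798 and 0.0118 to 0.0731), and PB119 was called in 1 (0.00870 to 0.453). Max had folds of 18.7, 18.2 and 8.26. The repressor gene Mnt had 15.3, 21.7 and 15.7, Mlxip had 16.7, 26.0 and 15.4, and Mga had 13.4, 17.0 and 15.3. Myc, Mycn and Mycl had no peak within 1000 bp of an end in any line. The summit nearest to Myc lay 47.7 kb beyond the gene in each of the 3 lines. It stood at 62038047 on chromosome 15 in PB115, 61 bp inside the end of the long noncoding RNA gene Pvt1 that faces Myc, and had a fold of 31.8 in PB115, 42.5 in PB119 and 7.99 in PB120. It ranked at percentile 99.4 of fold in PB115, 99.8 in PB119 and 34.8 in PB120. The summit held 157, 189 and 58 fragments in the same order, and the PB120 value exceeded the upper quartile of that list, 52 fragments. Fold divides by local input background, so the low PB120 rank does not by itself show a weak ChIP signal there. Odc1, the ornithine decarboxylase gene and a classic target of c-Myc, had folds of 15.8, 27.1 and 10.3, the last from a different peak at the same end.

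Genes repressed by MYC with MIZ1 had 9, 12 and 9 of 22 members bound and passed the test with 1000 bp windows in PB120 (odds ratios 2.24, 2.20 and 3.52; adjusted p 0.0912, 0.0908 and 0.00933). Gadd45g had folds of 15.5, 17.9 and 11.8, Cdkn2a, the locus of the p16 and p19 tumour suppressors, had 19.6, 28.1 and 9.64, and Cebpa had 12.7, 21.3 and 12.1. The list was called in 5 of 6 alternatives in PB120 (adjusted p 0.0107 to 0.0501), in 3 in PB115 (0.0193 to 0.188) and in 2 in PB119 (0.0192 to 0.121). Of 22 genes of p53 targets and apoptosis, 6, 11 and 3 were bound, without a call in any line (odds ratios 1.21, 1.83 and 0.802; adjusted p 0.670, 0.205 and 1.00). With windows of 5000 bp the list was called in PB119 (odds ratio 3.61, adjusted p 0.00781, range over 6 alternatives 0.00781 to 1.00). Trp53 had folds of 23.6, 17.6 and 17.3 at a summit shared with Wrap53, Bax had 14.0, 16.1 and 17.6, and Bcl2l11 had 10.2 in PB115, 13.7 in PB119 and no peak within 1000 bp of an end in PB120.

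**Figure D3:**
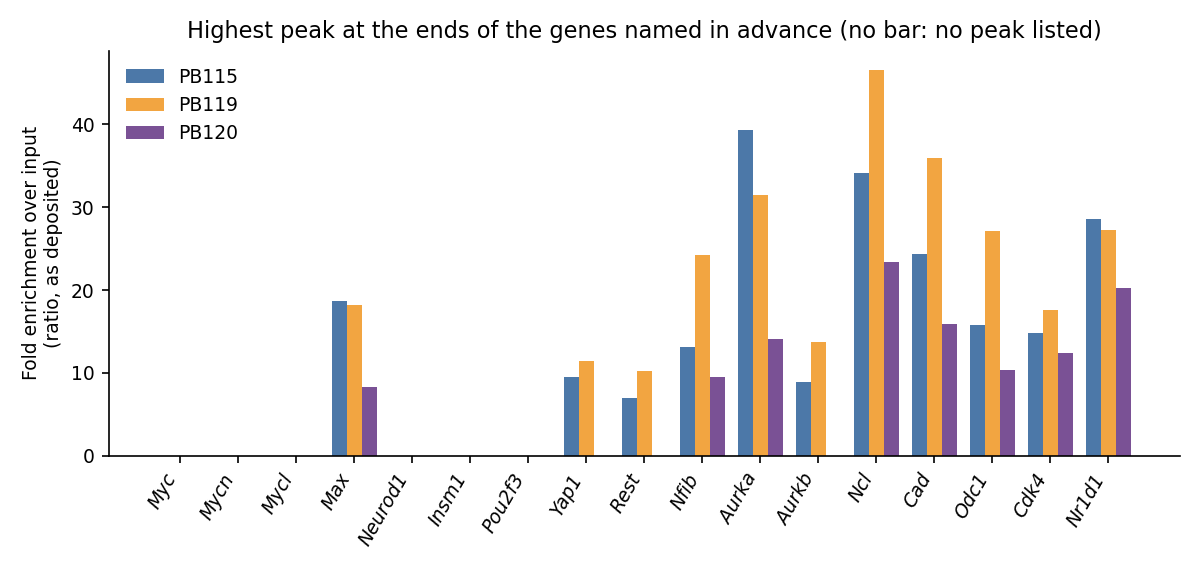
Fold enrichment over input as deposited (vertical axis, ratio) of the highest peak within 1000 bp of an end of each of 17 genes named in advance (horizontal axis), with a bar per line and no bar where no peak was listed. Ncl reaches 34.2, 46.6 and 23.4 in PB115, PB119 and PB120, and Myc, Mycn, Mycl, Neurod1, Insm1 and Pou2f3 have no bar.

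Over the 19 lists, 10 were bound more often than other genes in PB115, 11 in PB119 and 11 in PB120, and 3, 5 and 3 less often. A p of 1e-20 lowered the counts to 7 more often and 1 less often in PB120 and to 3 less often in PB119, and counting summits inside genes also left 3 less often in PB119. Whether a list differed between lines was tested among the genes bound in only 1 line of each pair. No list was called different in the 57 Fisher tests. In 3 of them the unadjusted p was under 0.05, and the smallest adjusted p was 0.61. These tests could find only an excess of members in the line with fewer genes bound alone. In 7 of the 57 no member was bound in only 1 line. With every such member in the line with more genes bound alone, the smallest p any test could give was 0.226. Whether the lists that passed in some lines and not in others (mitotic, Notch, neuroendocrine, alveolar, fibroblast, MYC network and MIZ1) differ between lines was therefore not decided. With windows of 500 bp, 1 test was called. There the translation list made up 4 of the genes bound in PB120 and not in PB119 beside 133 other genes, and 8 of those bound in PB119 and not in PB120 beside 3778 others (odds ratio 0.0704, adjusted p 0.0323).

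The peaks of highest pileup were not those of highest fold, with an exception in PB119. In PB115 and PB120 the top 3 all lay between 39843082 and 39846656 on chromosome 17 beside Rn18s-rs5, a ribosomal RNA pseudogene, with 273 to 294 fragments but folds of 1.82 to 2.87. Input background at the listed peaks of this locus was 33.6 to 64.0 times the genome-wide level in PB115, 25.7 to 46.4 times in PB119 and 67.2 to 88.7 times in PB120. In PB119, 2 of the top 3 lay there, with folds of 2.84 and 4.88. The remaining PB119 peak, at 142367216 to 142368080 on chromosome 5, held 267 fragments at a fold of 60.9, the highest of its list. It lay 457 bp from the noncoding gene Gm31068 and 33840 bp from an end of Foxk1, and overlapped peaks with folds of 38.4 in PB115 and 26.7 in PB120.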

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

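The comparison of chromosomes, and the tests of gene density and of a single locus below, were chosen after the data were seen.

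Of 60 Fisher tests of the share of peaks per chromosome between pairs of lines, 4 passed after adjustment, and each is a difference between the peak lists of a pair of lines, with 1 library per line. Chromosome 8 held 8.20% of the PB120 peaks against 5.12% in PB115 (odds ratio 0.604 for PB115 against PB120, adjusted p 9.19e-11) and 5.20% in PB119 (odds ratio 0.613 for PB119 against PB120, adjusted p 4.18e-12). Chromosome 13 held 3.93% of the PB119 peaks and 2.98% of the PB120 peaks (odds ratio 1.33, adjusted p 0.0297). Chromosome X held 1.41% in PB119 and 0.697% in PB120 (odds ratio 2.04, adjusted p 0.000712).

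The chromosome 8 excess of PB120 was present in regions listed by PB120 alone, of which 78 of 567 (13.8%) lay there, and in the signal at regions common to all lines, where PB120 input background relative to the other lines was higher on chromosome 8 than on chromosomes other than 3 and 8 by 0.22 on the log2 scale and ChIP fragments by 0.34 (permutation p 1e-04 for both, the smallest that 10000 resamples can give). Chromosome 3 also had a rise in background, of 0.17 (permutation p 1e-04, adjusted p 0.00036), with a difference of 0.06 in ChIP fragments (adjusted p 0.221). Away from gene ends the rise in background was 0.33 on chromosome 8 (adjusted p 0.00036) and 0.11 on chromosome 3 (adjusted p 0.264). A single amplified or repeated locus did not account for it, since the 5 Mb bin with most PB120-only regions held 19.2% of them and 19 bins held at least 1. Input that favoured gene-dense chromatin did not account for it either. Of the 8 chromosomes with a higher gene density, 0 reached its background. The highest median log2 ratio of PB120 to the other lines among them was 0.16, against 0.35 on chromosome 8. Less gene-dense chromosomes were left out of that test, and 3, 10, 18 and 13 had 0.30, 0.24, 0.21 and 0.20. The others of lower density had −0.04 (X) to 0.19 (chromosome 12). Another kind of input bias was therefore not excluded as a source of the chromosome 8 excess. More copies of chromosome 8, or of a large part of it, in PB120 than in the other lines may account for it: the excess of ChIP fragments it needs was found at regions away from gene ends as well, at 0.51 on the log2 scale. Only 10 of 16 bins with at least 5 common regions had a background above that of the other chromosomes, so whether the whole chromosome is involved stays open, and the lines' karyotypes were not analysed here.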

How the results depend on the processing

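The alternatives with a p of 1e-20 or smaller, summits anywhere in a gene, a limit on input background and removal of chromosome 8 were chosen after the data were seen. Among the main results, 69 values kept their direction and side of the threshold or stayed within the tolerance, 23 moved and none of these reversed. The tolerance was wide for counts. A fall from 7830 to 5589 PB115 peaks at a p of 1e-20 stayed within it. So did a fall from 3748 to 2816 common regions with the same number of peaks per list. A p of 1e-20 left 3369 peaks in PB120, 2419 regions common to all lines and 2060 genes bound in both PB115 and PB120, because fewer peaks were counted. It also left 7 lists over-represented and 1 under-represented in PB120, and 3 under-represented in PB119. The cause of these list counts was not tested, and the same number of peaks per list left 4 under-represented in PB119. Reciprocal overlap of at least 50% gave 2186 common regions, and leaving out each line in turn gave 3813 to 7255, with the highest value without PB120. With the same number of peaks per list, PB115 and PB119 shared 3278 bound genes. The share of summits near a gene end in PB115, PB119 and PB120 was 53.4%, 49.6% and 56.1% with 500 bp, 77.4%, 74.6% and 75.7% with 5000 bp, 68.4%, 65.0% and 67.7% with the ends of all annotated genes, and 87.6%, 86.1% and 85.2% with summits in the gene counted, as wider or narrower windows must give. With summits in the gene counted, 3 lists were under-represented in PB119, and with 500 bp windows 1 list was called different between lines; the cause was not tested. Single list calls changed in 32 cases to no call and in 12 cases to a call without a change of direction, and 337 results for single lists and genes stayed as they were. Direction changed in 10 cases. The Notch list, called in PB119, went from over- to under-represented there without a call (11.5% of members bound) with the same number of peaks per list. The others had no call in either setting, all in PB120 except as given: Notch with 19.2% (PB115) and 15.4% at 500 bp, 30.8% at 5000 bp and 34.6% with summits in the gene counted; mitotic with 15% at 500 bp and at a p of 1e-20 and 25.0% at 5000 bp; p53 with 27.3% at 5000 bp and 22.7% with summits in the gene counted. The 2 named genes that moved were Ncl, with a summit within 500 bp of an end in 1 line, and Aurkb, with a summit within 5000 bp in 3. A q of 1e-5, with a lowest −log10 q of 6.81 in any list, and a limit to chromosomes 1 to 19, X and Y removed no peak, so they tested nothing and are left out of these counts. Settings that need a genome sequence, a CpG-rich background and E-box windows of other sizes or without repeats, were not run. No paired analysis was possible because each line had 1 ChIP library. Depth limits what can be called absent, since summits with fewer than 19 fragments were listed in no line.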

Other observations

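All gene groups, noncoding genes and peaks in the paragraphs that follow were chosen after the data were seen, and the tests of list length were set before their results.

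Several gene families were bound more often than other genes. Of these, the mitochondrial ribosomal proteins and the DEAD-box helicases share 7 and 3 members with the fixed lists. RNA exosome subunits, which degrade and trim RNA, had 9, 10 and 7 of 10 genes bound in PB115, PB119 and PB120 (Fisher adjusted p over 16 groups and 3 lines 4.81e-05, 7.17e-05 and 0.000434), led by Exosc5. Mitochondrial ribosomal proteins had 52, 66 and 34 of 78 bound (odds ratios 6.52, 10.2 and 3.95), DEAD-box helicases 23, 28 and 21 of 37 (5.33, 5.72 and 6.70), splicing factors 22, 26 and 15 of 32 (7.13, 7.97 and 4.50), importins and exportins 14, 15 and 11 of 20 (7.56, 5.51 and 6.23), and proteasome subunits 22, 34 and 21 of 51 (2.46, 3.68 and 3.57), with a largest adjusted p of 0.00365. Of 39 Hox genes 0 were bound in any line (adjusted p 8.61e-05, 4.24e-07 and 0.00274), and of 53 keratin genes only Krt80, in PB119 (largest adjusted p 0.000221). Cytochrome P450 genes had 5, 5 and 3 of 99 bound (odds ratios 0.171, 0.0969 and 0.158, largest adjusted p 0.000113). Core histone genes had 9, 23 and 5 of 57 bound, without a call in any line (adjusted p 0.230, 0.506 and 0.170), and the same held for V-ATPase subunits, with 9, 11 and 8 of 23, and Zfp zinc finger genes, with 98, 154 and 60 of 397. RNA polymerase II subunits had 8, 10 and 6 of 13 bound (largest adjusted p 0.0158). Respiratory complex I subunits had 15, 27 and 15 of 40 (adjusted p 0.0717, 8.81e-05 and 0.00287), and chaperonin and prefoldin subunits 11, 13 and 8 of 23 (adjusted p 0.0158, 0.0579 and 0.0524).

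Transfer RNA genes stood out among noncoding genes. Of 341 tRNA genes more than 2000 bp from the end of a coding gene, 34 (9.97%) had a summit within 1000 bp in PB115, 72 (21.1%) in PB119 and 30 (8.80%) in PB120, at 25, 50 and 20 distinct peaks with median folds of 9.54, 9.40 and 8.77. The shares for snoRNA genes placed likewise were 0.682%, 0.767% and 0.597%, for miRNA genes 2.13%, 3.34% and 1.21%, and for lncRNA genes 3.79%, 6.24% and 2.49%. Fisher odds ratios of tRNA against lncRNA genes were 2.81, 4.02 and 3.78, with adjusted p of 6.96e-07, 1.69e-18 and 1.06e-08. Genes of 1 tRNA cluster can share a peak, so these genes are not independent.

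Further sites of high fold lay at Snhg15, a host gene of small nucleolar RNA, with 45.0 in PB115, at Pemt, a phospholipid synthesis gene, with 57.3 in PB119, and at Utp25, a ribosome biogenesis gene, with 39.5 in PB120, the highest of that list. Each of these peaks overlapped peaks in both other lines.

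PB119 listed 2.62 times as many peaks as PB120, and technical differences between the libraries were set against this. Lower ChIP sequencing depth in PB120, 0.793 times that of PB119, did not account for it. Of the 13527 PB119 peaks, 12976 still passed a p of 1e-10 at the PB120 tag numbers. Depth together with the higher recovered input background of PB120 (a ratio of 1.15 at common regions) left 12384. PB120 also had the smaller input (26156520 against 37979638 tags in PB119), and this ratio was not separated from input depth. Input tags, 28380432 in PB115, ranked the 3 lines as their list lengths did, so an effect of input depth on list length stays open. Lower ChIP enrichment in PB120 may account for part of it: at common regions PB120 held 0.776 times the ChIP fragments of PB119 per tag, and scaling by this as well left 8638, against 5168 peaks in the PB120 list. This cannot be told apart from fewer c-Myc sites in PB120, because common regions are those that passed the cutoff in PB120, so the ratio there overstates its enrichment and the bound set for this test was wrong by design; a biological difference between the lines stays open as untested.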
